A study of Homo sapiens with 9 samples.

How the data were processed

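The study profiled RNA bound by Argonaute, the protein that carries microRNAs to their target transcripts, in 3 established breast carcinoma cell lines. The assay was HITS-CLIP, in which RNA is cross-linked to the protein, recovered by immunoprecipitation and sequenced, so that stacks of reads mark the bound positions. The 9 samples were 3 each of MCF7, BT474 and MDA-MB-231, none of them treated. Per the labels' protocols, MCF7 cells grew in a different basal medium from the other 2 lines, with the same share of serum.

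The deposited data used here were 1 BED list of 111916 peaks for the whole series. Each row holds a chromosome, a start, an end, a strand and the name of a peak set, and the set names are those of the cell lines, with MDA231 read as MDA-MB-231. Reads were aligned with Novoalign to hg19, per the submitters' processing notes, which give no version. The peak caller, its threshold, the treatment of reads with several possible positions and the way in which the replicates were joined are not given in the sources used here. The score column that the authors deposited is 0 in every row, so it carries no peak height and no significance. The list has 0 columns that tell replicates apart, and each cell line was therefore treated as 1 pooled set. No mean ± SD over replicates, no leave-one-out value and no test between cell lines against replicate error could be computed. Nothing in the sources used here says whether the 3 samples of a line came from separate cultures. Sequencing depth per sample is unknown. The only measure of size is the number of peaks per line, which was 48172 in MCF7, 55161 in BT474 and 8581 in MDA-MB-231, with 2 further MCF7 entries, under a set name that marks them as checked sites, that entered no comparison.

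The tests planned before the data were examined included count models, peak positions in transcript regions, microRNA seed matches, gene lists and peak scores. They need counts, scores, an hg19 genome or an hg19 annotation, none of which was used here, so they were not run and the rule for named genes could not be applied. No peak was assigned to a gene. The reference gene table (GRCh38.p14) was used only for the chromosome on which a gene named in connection with the labels lies, because its coordinates belong to another build. What remained of the plan was the description of the peak sets and the overlap of the sets of the 3 lines. Regions are named by a rule set after the layout of the list and a first count of its windows had been seen. It takes the 5 windows of 1 Mb with the largest ratio in each direction per pair of lines, among windows with at least 40 peaks of the pair, the 5 clusters with most peaks, and for each line the 5 clusters with most peaks and none of another line. The interval in the header of the list and the 2 entries set apart were named in any case. The region of chromosome 17 from 35 to 38 Mb and chromosome 16 were singled out after their values were seen.

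Starts were converted to 1-based positions. Peaks of 2 lines were called shared when they overlapped by at least 1 bp on the same strand. Chance overlap was measured by moving 1 list along the chromosomes by 200, 1000, 10000 or 100000 bp and counting again. Overlapping same-strand peaks of any line were joined into loci, and same-strand peaks with gaps of at most 1000 bp into clusters. For chromosomes and windows, the share of a line's peaks was divided by the share in another line. Intervals in square brackets are exact 95% Clopper-Pearson intervals, of a share or of the ratio of 2 counts. They cover counting error only, and they are too narrow as statements about the cell lines, because peaks lie in clusters and because culture and library differences between the samples are not in them. A count of 0 peaks means that none passed the authors' threshold, so no limit was set on it. Random thinning of a list used 20 draws. It scales an overlap by the part of the list that is kept, so it does not stand for lower depth or a stricter threshold.

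Correlations between adjacent windows of 1 Mb used windows with at least 20 peaks of the pair and the log2 ratio of shares after adding 0.5 to each count. They were set against 10000 shuffles of the windows within each chromosome. Peaks at a constant offset between 2 places were counted with a tolerance of 3 bp on peak centres. Alternatives were an overlap of 50% of both peaks, merging of peaks within 50 bp, strand ignored, peaks of 61 bp only, chromosomes Y and M left out, clusters of 10 or more peaks left out, lists thinned to equal size, clusters counted 1 time per line and windows of 0.5 or 2 Mb. The computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

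The functions were tested on simulated data made from the 48172 MCF7 peaks. Simulated shares of shared peaks of 9.94%, 29.8% and 60% were recovered as 10.3%, 30.2% and 60.2%, most of the difference being chance overlap. Simulated regional excesses of 2-fold and 5-fold were recovered as 2.01-fold and 5.10-fold. With the line names shuffled over all 111914 peaks, the correlation of adjacent windows was -0.03.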

Results

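Argonaute-bound positions were compared between MCF7, labelled as estrogen receptor positive, BT474, labelled as Her2 amplified, and MDA-MB-231, labelled as triple negative. The title of the study places the comparison in the context of nuclear receptor signalling. The list held 55161 peaks in BT474, 48172 in MCF7 and 8581 in MDA-MB-231. BT474 thus had 1.15 times as many peaks as MCF7 and 6.43 times as many as MDA-MB-231, and MCF7 had 5.61 times as many as MDA-MB-231. Each number stands for 1 list pooled over 3 samples, so the spread between replicates could not be set against any difference below.

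Most peaks of each line had the same width. A width of 61 bp was found for 96.3% of MCF7, 96.6% of BT474 and 98.5% of MDA-MB-231 peaks, and the widest peak spanned 170 bp in MCF7, 802 bp in BT474 and 229 bp in MDA-MB-231. The plus strand held 53.3% [52.9, 53.8] of MCF7, 55.0% [54.6, 55.4] of BT474 and 53.3% [52.2, 54.3] of MDA-MB-231 peaks. On chromosome X the plus strand held 72.9% of BT474 peaks, against 60.3% in MCF7 and 58.5% in MDA-MB-231. Fewer than 1 peak in 200 overlapped a peak of the same line on the opposite strand (0.361% in MCF7, 0.228% in BT474 and 0.385% in MDA-MB-231). Peaks lay close together in the larger lists. Another peak of the same line and strand lay within 1000 bp of 40% of MCF7, 37.4% of BT474 and 21.6% of MDA-MB-231 peaks.

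The first comparison asked how many bound positions MCF7 and BT474 had in common. In MCF7, 17325 of 48172 peaks overlapped a BT474 peak, or 36% [35.5, 36.4]. In BT474, 31.5% [31.1, 31.9] overlapped an MCF7 peak. Moving the BT474 list by 10000 bp left 0.691% of MCF7 peaks with an overlap, so the observed number was 52.0 times that after this move. Moving it by only 200 bp left 7.09%, and the observed number was 5.07 times that. Shared peaks coincided closely, with a median distance of 6 bp between the starts of 15530 pairs of 61 bp peaks and identical positions in 12.2% of them. Peaks with a neighbour in the same line within 200 bp were shared with another line more often (49.1% [48.2, 50.1] in MCF7 and 47.5% [46.6, 48.4] in BT474) than peaks with no neighbour within 100000 bp (35.6% [34.3, 36.9] and 27.2% [26.1, 28.4]). The share was lowest with the nearest neighbour between 10000 and 100000 bp away (31.7% [30.8, 32.6] and 24.4% [23.7, 25.1]).

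The second comparison set the triple negative line against the other 2. Most MDA-MB-231 peaks had a counterpart. Of the 8581 peaks, 57.6% [56.5, 58.6] overlapped an MCF7 peak and 60.6% [59.6, 61.6] a BT474 peak, while 47.0% [45.9, 48.1] overlapped both. Only 28.8% [27.9, 29.8] overlapped neither, against 62.2% [61.8, 62.6] of MCF7 and 66.5% [66.1, 66.9] of BT474 peaks that were found in no other line. Each list was searched against partners of other lengths, so these 3 shares do not compare the lines at equal length, and in the reverse direction only 10.3% of MCF7 and 9.45% of BT474 peaks overlapped an MDA-MB-231 peak. Chance overlap after a move of 10000 bp was 0.688% with MCF7 and 0.792% with BT474, and after a move of 200 bp 8.52% and 9.15%. The BT474 list is 1.15 times as long as that of MCF7. With BT474 thinned at random to the number of MCF7 peaks, the share was 53.0% ± 0.271 (SD over 20 draws), below that with MCF7, a value that random thinning sets by construction. The order of the 2 shares thus turns with the treatment of list length, and neither line is taken as the closer one.

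**Figure D1:**
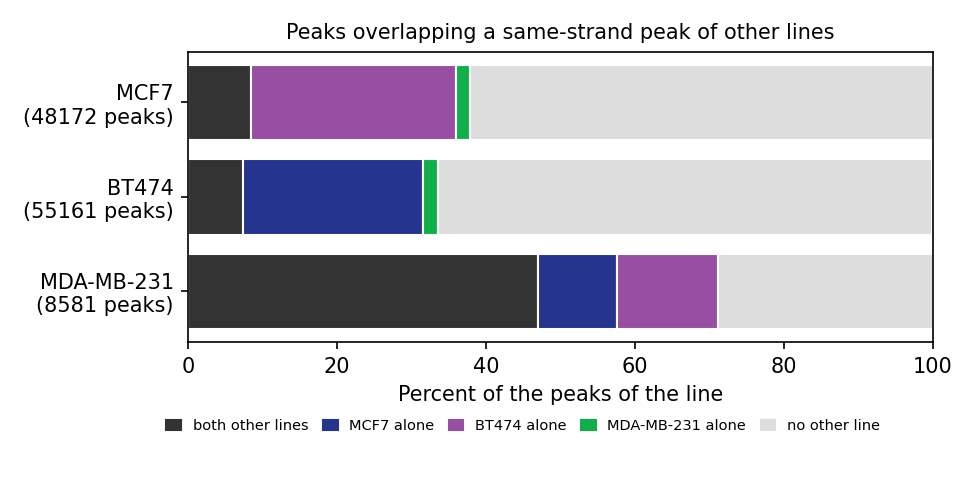
Percent of the peaks of each cell line (x axis) that overlap a same-strand peak of both other lines, of 1 other line alone or of none. The part found in no other line is 62.2% in MCF7, 66.5% in BT474 and 28.8% in MDA-MB-231.

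Joining overlapping peaks gave 88193 loci. All 3 lines had a peak at 4108 of these (4.66%), MCF7 and BT474 alone shared 13041 (14.8%), and 1094 and 855 were shared by MDA-MB-231 with BT474 alone and with MCF7 alone. Loci found in 1 line only numbered 36656 in BT474, 29964 in MCF7 and 2475 in MDA-MB-231. A locus seen in both MCF7 and BT474 was also in the MDA-MB-231 list in 24.0% [23.3, 24.6] of cases. Loci of MCF7 without BT474 were there in 2.77% [2.59, 2.96] of cases and loci of BT474 without MCF7 in 2.90% [2.73, 3.07].

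The distribution over chromosomes differed between the lists. Between BT474 and MCF7 the interval of the ratio excluded 1 for 18 of 25 chromosomes, 10 of them with the higher share in BT474 and 8 with the higher share in MCF7. The 10 include chromosome Y, for which no values are given. Chromosome 16 held 5.60% of MCF7 and 3.78% of BT474 peaks, a ratio of 1.48 [1.40, 1.57] towards MCF7, and chromosome 21 had a ratio of 1.34 [1.20, 1.5] in the same direction. Among the others, higher in BT474 were chromosome 22 (ratio 1.44 [1.31, 1.57]), chromosome 18 (1.42 [1.28, 1.58]) and chromosome X (1.31 [1.25, 1.39]). For chromosome 17 as a whole the interval held 1 (1.03 [0.983, 1.09]). The ratio of MDA-MB-231 to MCF7 excluded 1 for 15 chromosomes and that to BT474 for 12. Chromosome 6 was higher in MDA-MB-231 than in MCF7 (1.36 [1.24, 1.5]) and BT474 (1.40 [1.28, 1.54]).

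**Figure D2:**
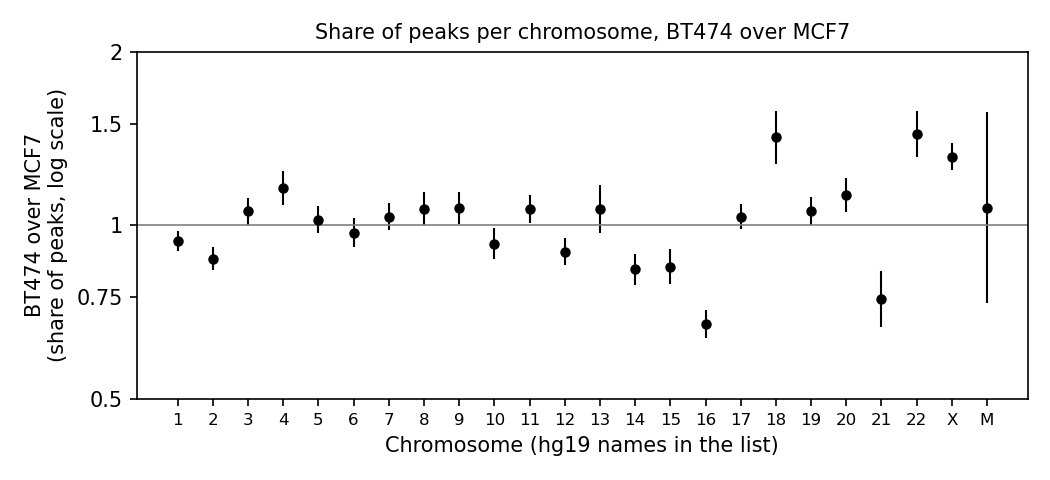
Share of peaks per chromosome (x axis) in BT474 divided by that in MCF7 (y axis, log scale), with exact 95% intervals for counting error. Chromosome 16 lies lowest at 0.674 and chromosome 22 highest at 1.44. Chromosome Y is left out.

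The mitochondrial chromosome carried almost the same number of peaks in every list, 53 in MCF7, 65 in BT474 and 62 in MDA-MB-231. As a share of its list this was 0.722% in MDA-MB-231, 6.57 times [4.48, 9.66] the share in MCF7 and 6.13 times [4.26, 8.82] that in BT474. With counts so alike, these ratios mostly restate the lengths of the lists. The MCF7 and BT474 lists were 5.61 and 6.43 times as long as that of MDA-MB-231.

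Because BT474 is labelled as Her2 amplified and the gene of that receptor, ERBB2, lies on chromosome 17, windows along this chromosome were compared. The stretch from 35 to 38 Mb, singled out after its counts were seen, held 477 BT474, 83 MCF7 and 30 MDA-MB-231 peaks. The share of BT474 peaks there was 5.02 times [3.97, 6.42] that of MCF7 and 2.47 times [1.71, 3.71] that of MDA-MB-231. The window from 37 to 38 Mb had the most peaks of any window in BT474 (220, against 36 in MCF7 and 20 in MDA-MB-231), followed by the window from 36 to 37 Mb (158, against 27 and 6). From 37 to 38 Mb MDA-MB-231 was also above MCF7 (ratio 3.12 [1.71, 5.53]), and BT474 was only 1.71 times [1.08, 2.86] MDA-MB-231. From 35 to 36 and from 36 to 37 Mb the interval of MDA-MB-231 over MCF7 held 1 (1.12 [0.279, 3.35] and 1.25 [0.421, 3.08]). The window from 38 to 39 Mb was closer to even, with 87 BT474 and 49 MCF7 peaks (ratio 1.55 [1.08, 2.25]), while the window before the stretch, from 34 to 35 Mb, was at 2.13 [1.37, 3.37]. BT474 was also higher from 47 to 48 Mb (1.87 [1.28, 2.77]), from 48 to 49 Mb (1.69 [1.17, 2.48]), from 52 to 53 Mb (3.12 [1.31, 8.54]) and from 53 to 54 Mb (33 against 6 peaks, 4.80 [1.99, 14.0]). The same held from 9 to 10 Mb (9 peaks against 1, 7.86 [1.09, 344.5]) and from 33 to 34 Mb (1.67 [1.001, 2.87]). Between 35 and 38 Mb both strands took part, with ratios of 5.43 [3.82, 7.91] on the plus and 4.69 [3.41, 6.57] on the minus strand. Counting each cluster of peaks 1 time per line, the ratio was 3.55 [2.67, 4.77]. Further along the chromosome the window from 58 to 59 Mb had the most peaks of any window in MCF7, 143 against 85 in BT474 and 6 in MDA-MB-231. The next 3 windows were also higher in MCF7 than in BT474, with ratios of 3.13 [2.09, 4.79], 2.15 [1.44, 3.24] and 3.12 [2.08, 4.81]. So were those from 1 to 2 Mb (1.44 [1.04, 2.01]), 7 to 8 Mb (1.865 [1.37, 2.55]), 54 to 55 Mb (2.86 [1.05, 9.01]), 65 to 66 Mb (1.73 [1.16, 2.61]) and 73 to 74 Mb (1.60 [1.14, 2.25]). Between BT474 and MCF7, none of these windows was among the 5 with the largest ratio genome-wide in either direction. Between MCF7 and MDA-MB-231, the window from 59 to 60 Mb (93 MCF7 and 0 MDA-MB-231 peaks) was among the 5 furthest towards MCF7. Whether any of the windows named along chromosome 17 holds ERBB2 was not read from the coordinates.

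**Figure D3:**
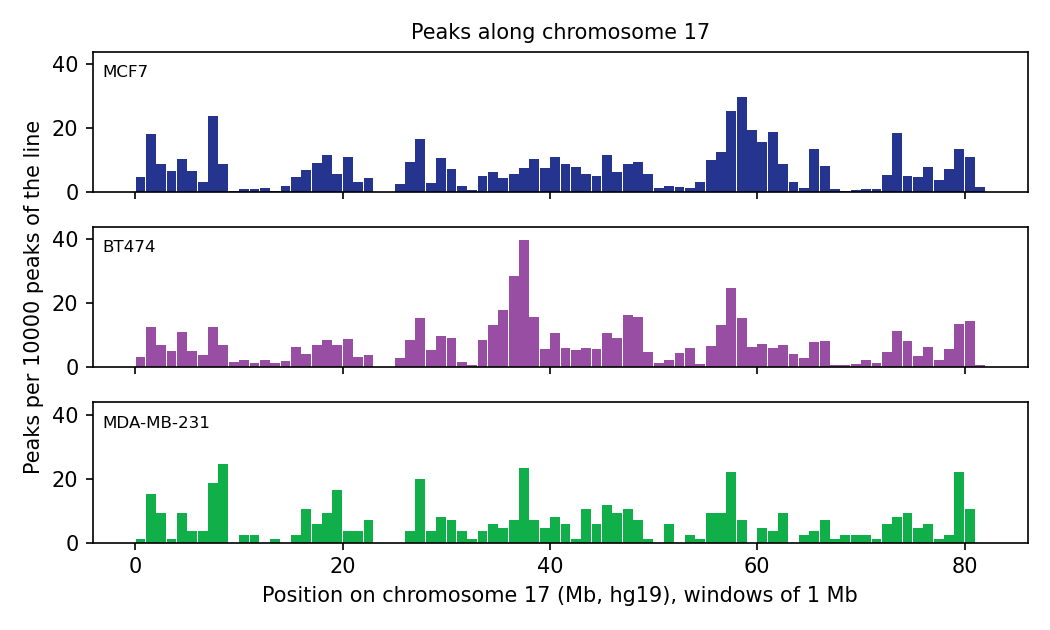
Peaks in windows of 1 Mb along chromosome 17 (x axis, hg19), as peaks per 10000 peaks of the line (y axis), for MCF7, BT474 and MDA-MB-231. BT474 stands out between 35 and 38 Mb, where it has 477 peaks and MCF7 has 83.

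Over the genome, 917 windows had at least 40 MCF7 and BT474 peaks together. The ratio of shares was above 2-fold towards BT474 in 56 and above 2-fold towards MCF7 in 61, and the interval lay entirely beyond 2-fold in 15 and 16 windows. How reads with several possible positions were placed is not given, so their part in the windows named here and below cannot be told. The 5 windows with the largest ratio towards BT474 were at 42 to 43 Mb of chromosome 10 (93 BT474 and 4 MCF7 peaks, ratio 20.3 [7.67, 76.1]), 61 to 62 Mb of chromosome 7 (142 and 7, 17.7 [8.38, 44.9]), 27 to 28 Mb of chromosome 19 (56 and 3), 48 to 49 Mb of chromosome 11 (39 and 2) and 43 to 44 Mb of chromosome 8 (43 and 3). In the first of these, 1 cluster of 41 BT474 peaks made up much of the count. The 5 windows with the largest ratio towards MCF7 were at 117 to 118 Mb of chromosome 10 (43 MCF7 peaks and 1 BT474 peak), 51 to 52 Mb of chromosome 11 (50 and 3), 127 to 128 Mb of chromosome 12 (56 and 7, ratio 9.16 [4.17, 23.8]), the window of chromosome 6 that holds the interval in the header of the list (62 and 8, 8.87 [4.24, 21.5]) and 186 to 187 Mb of chromosome 1 (37 and 5, 8.47 [3.32, 27.6]).

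Against MCF7, MDA-MB-231 was highest at 61 to 62 Mb of chromosome 7 (35 against 7 peaks, ratio 28.1 [12.3, 74.9]), where BT474 was also high, then on the mitochondrial chromosome, at 133 to 134 Mb of chromosome 2 (25 and 28 peaks, 5.01 [2.80, 8.92]), at 161 to 162 Mb of chromosome 1 (34 and 50, 3.82 [2.39, 6.02]) and at 27 to 28 Mb of chromosome 6 (74 and 119, 3.49 [2.58, 4.71]). The chromosome 2 and chromosome 6 windows were also high against BT474, with ratios of 4.87 [2.78, 8.44] and 4.53 [3.32, 6.16]. So were 148 to 149 Mb (4.31 [3.03, 6.10]) and 146 to 147 Mb (3.87 [2.64, 5.63]) of chromosome 1. In the other direction, MDA-MB-231 had 0 peaks at 59 to 60 Mb of chromosome 17 (93 in MCF7), 51 to 52 Mb of chromosome 11 (50), 117 to 118 Mb of chromosome 10 (43), 61 to 62 Mb of chromosome 20 (40) and 61 to 62 Mb of chromosome X (40). It also had 0 peaks at 92 to 93 Mb of chromosome 2 (66 in BT474), 54 to 55 Mb of chromosome X (47), 111 to 112 Mb of chromosome 6 (43) and 50 to 51 Mb of chromosome 20 (41), and 1 peak at 164 to 165 Mb of chromosome 1 (58 in BT474).

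Grouping same-strand peaks of all lines within 1000 bp gave 62419 clusters, of which 41681 (66.8%) were single peaks and 697 held 10 or more peaks. All 3 lines contributed to 474 of the 697 (68.0%). Another 189 had peaks of MCF7 and BT474 without MDA-MB-231. Clusters were built and ranked on the pooled peaks of all lines. This favours clusters with several lines, so neither the 68.0% nor the ranking measures how often large clusters are shared. The clusters with most peaks were common to the 3 lines. They lay on chromosome 11, minus strand, from 62283382 to 62301357 (35 MCF7, 41 BT474 and 22 MDA-MB-231 peaks), on the mitochondrial plus strand from 4408 to 16104 (32, 33 and 33), on chromosome 11, plus strand, from 65266503 to 65273489 (20, 33 and 19) and from 65190449 to 65198647 (12, 26 and 13), and on chromosome 1, plus strand, from 564660 to 570250 (18, 21 and 23).

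Clusters of 10 or more peaks that came from a single line numbered 17 in BT474, 5 in MCF7 and 1 in MDA-MB-231. These numbers also depend on the lengths of the lists. The 5 largest of BT474 lay on chromosome 1 from 384371 to 386674 (27 peaks), chromosome 14 from 105695196 to 105700884 (26), chromosome 6 from 170965471 to 170970600 (24), chromosome 5 from 180811002 to 180813227 (21) and chromosome 15 from 102432880 to 102434787 (18). More than 50% of the peaks in the clusters of chromosomes 5 and 15 lay at a constant offset from peaks of the chromosome 1 cluster. The 5 largest of MCF7 lay on chromosome 21 from 47712464 to 47714522 (21 peaks), chromosome 12 from 127218435 to 127224653 (17), chromosome 1 from 109792876 to 109795961 (14), chromosome 11 from 1264449 to 1268598 (11) and chromosome 9 from 141121846 to 141123722 (10). In MDA-MB-231 a cluster of 12 peaks lay on chromosome 12 from 528694 to 531267. The next 4 held 3 or 4 peaks each, on chromosome 10 from 50611598 to 50611975 (4) and from 17271314 to 17271781 (3), chromosome 11 from 65659682 to 65660492 (3) and chromosome 13 from 109919877 to 109920682 (3).

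The header of the list opens a genome browser at chromosome 6 from 152419593 to 152424819, an interval of 5227 bp. ESR1, the gene of the estrogen receptor, is on this chromosome, but the interval was not matched to an annotation. It held 9 MCF7 peaks, 3 BT474 peaks and 0 MDA-MB-231 peaks, all 12 on the plus strand. Each of the 3 BT474 peaks overlapped an MCF7 peak, at 152420412 to 152420472, 152421741 to 152421801 and 152422291 to 152422351. The window of 1 Mb around it held 62 MCF7, 8 BT474 and 1 MDA-MB-231 peaks.

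**Figure D4:**
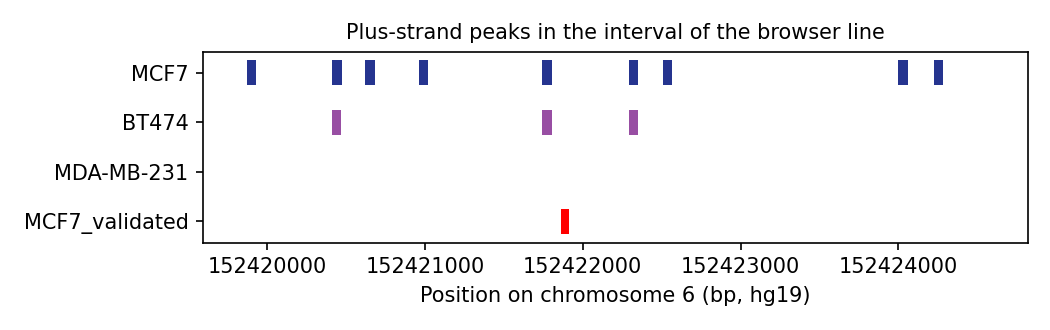
Plus-strand peaks between 152419593 and 152424819 on chromosome 6 (x axis, hg19), 1 bar per peak and 1 line per peak set. MCF7 has 9 peaks, BT474 has 3, MDA-MB-231 has 0, and the MCF7 entry marked as checked (red) lies 60 bp past a peak shared by MCF7 and BT474.

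The list also holds 2 MCF7 entries under a set name that marks them as checked sites, both on the plus strand. Neither overlapped a peak of the MCF7 list. The entry on chromosome 6 spanned 152421862 to 152421911 (50 bp). The nearest MCF7 peak and the nearest BT474 peak, both at 152421741 to 152421801, ended 60 bp before it. The entry on chromosome 20 spanned 46250989 to 46251079 (91 bp). It overlapped a BT474 peak at 46251034 to 46251094, while the nearest MCF7 peak, at 46252689 to 46252749, began 1609 bp beyond its end, and the nearest MDA-MB-231 peak was 32648 bp away. How these entries were checked is not given in the sources used here.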

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

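No paired analysis was possible because the list pools the replicates of each line. For the same reason no replicate could be left out or used as a block. Other count models, filters and pseudocounts, peaks of the highest scores, and alternatives on annotation, seed matches, gene lists or target pairs were intended but not run, because they need counts, scores or an hg19 reference. All alternatives except the 50% overlap and the merging of peaks within 50 bp were chosen after seeing the data. Over 15 results and 86 alternative values, 61 stayed within the interval of the reported value (or within 1.5 times a count, or 0.1 of a correlation) and 25 moved further. The share of MCF7 peaks found in BT474 was 31.4% with an overlap of 50% of both peaks, 33.5% with peaks of 61 bp only, 33.4% without clusters of 10 or more peaks and 5.66% with all lists thinned to the number of MDA-MB-231 peaks. In the same order, the share of MDA-MB-231 peaks found in MCF7 was 52.7%, 55.9%, 55.3% and 10.2%, and the share found in BT474 was 55.9%, 57.6%, 57.9% and 9.57%. Thinning left 118.2 loci common to the 3 lines on average, against 4108, as a thinned list holds fewer of the peaks to be shared. The causes of the other shifts were not tested. The thinned shares follow from the lengths of the lists, since the MDA-MB-231 list stays whole, and say nothing on which lines are most alike. The ratio of BT474 to MCF7 on chromosome 17 from 35 to 38 Mb was 3.55 with clusters counted 1 time per line and between 4.71 and 5.43 in the other alternatives. The ratios of the chromosome 6 window named in the report and of chromosome 16 stayed within their intervals in every alternative run. Without depth or peak heights, a stricter threshold could not be tried.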

Other observations

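The 10 Mb segments, the correlation of adjacent windows over all peaks, the test of the longer BT474 list and those of the MDA-MB-231 list were chosen after the result was seen, and the other tests after the list but before their own result. Beyond chromosome 17, broad stretches of chromosomes differed between BT474 and MCF7. Of 217 segments of 10 Mb with at least 200 peaks of the pair, the interval of the ratio lay above 1 in 57 and below 1 in 55. BT474 was highest at 50 to 60 Mb of chromosome 18 (158 BT474 and 45 MCF7 peaks, ratio 3.07 [2.19, 4.37]), then at 30 to 40 Mb of chromosome 17 (2.56 [2.22, 2.95]), 60 to 70 Mb of chromosome 8 (2.44 [1.80, 3.35]), 100 to 110 Mb of chromosome 11 (2.44 [1.80, 3.35]) and 10 to 20 Mb of chromosome X (2.39 [1.84, 3.13]). MCF7 was highest at 180 to 190 Mb of chromosome 1 (2.03 [1.56, 2.67]), 80 to 90 Mb of chromosome 16 (2.02 [1.70, 2.40]), 50 to 60 Mb of chromosome 15 (2.01 [1.65, 2.44]), 40 to 50 Mb of chromosome 21 (1.85 [1.52, 2.26]) and 110 to 120 Mb of chromosome 1 (1.83 [1.53, 2.19]).

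Against MCF7, MDA-MB-231 was highest at 20 to 30 Mb of chromosome 6 (182 peaks against 423, ratio 2.42 [2.02, 2.88]) and 140 to 150 Mb of chromosome 1 (2.29 [1.96, 2.68]). MCF7 was highest against it at 70 to 80 Mb of chromosome 16 (2.62 [1.70, 4.23]), and segments of chromosome 16 from 80 to 90 Mb (2.33 [1.60, 3.52]) and from 10 to 20 Mb (2.32 [1.59, 3.51]) were also among the 5 highest.

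Neighbouring windows of 1 Mb resembled each other in the ratio of BT474 to MCF7. Across 1164 pairs of adjacent windows, which are not independent replicates, Pearson's r was 0.36 and Spearman's rho 0.37, and windows shuffled within their chromosomes reached at most 0.18 (one-sided permutation p = 0.0001 for each, the smallest that 10000 shuffles give, Benjamini-Hochberg adjusted p = 0.00015 over 6 correlations). For MDA-MB-231 over MCF7 r was 0.21 (rho 0.21, permutation p = 0.0001, adjusted p = 0.00015), and for MDA-MB-231 over BT474 it was 0.08 (rho 0.09, permutation p of r = 0.0364, adjusted p = 0.0364). Clusters that cross a window border do not account for this, since r was 0.37 when each cluster was counted 1 time per line, against at most 0.23 after shuffling. On chromosome 17 from 35 to 38 Mb the longer BT474 list is already divided out of the ratio of 5.02, and the 3 largest clusters held only 8.81% of the BT474 peaks. Of 41 bins of 50 kb there, 40 (97.6%) had the higher share in BT474, but the stretch was singled out for its excess of BT474 peaks, so this count cannot tell whether the segment is gained in BT474. From 37 to 38 Mb MDA-MB-231 was also above MCF7 (3.12 [1.71, 5.53]), so the excess over MCF7 there was not particular to BT474. MCF7 held 36 peaks in that window, against 20 from 35 to 36 Mb and 27 from 36 to 37 Mb. Its count was thus not low beside the rest of the stretch. The windows from 35 to 36 and 36 to 37 Mb held only 4 and 6 MDA-MB-231 peaks. Their intervals (1.12 [0.279, 3.35] and 1.25 [0.421, 3.08]) are too wide to tell whether MDA-MB-231 was above MCF7 there too. Copy number and transcription were not measured, and the cause stays open.

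The MDA-MB-231 list may be short because fewer positions passed the threshold there, through lower depth or stricter detection. Loci of both other lines were 8.43 times as likely to be in it as loci of 1 other line (2.84%). A high ratio could also arise with fewer bound positions of the same set, so it does not single out lower depth or stricter detection. Of the MDA-MB-231 peaks, 28.8% lay apart from both other lists, and the reverse shares were 10.3% of MCF7 and 9.45% of BT474 peaks. All these shares depend on the lengths of the lists, and the short MDA-MB-231 list by itself keeps the reverse shares low. They thus cannot show a different set of bound positions or rule it out. A smaller number of bound positions of the same set cannot be told apart from lower depth, since the list has 0 columns of depth, counts or heights that vary.

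Some clusters found only in BT474 may come from reads of near-identical copies placed at several positions. Of the 10 largest such clusters, 6 had at least 50% of their peaks at a constant offset from peaks of another of the 10. Of 10 other clusters with 15 or more BT474 peaks, 0 did. These were not matched on length. The 6 spanned 1592 to 2304 bp and the shortest of the others 2427 bp, so the 0 of 10 does not measure chance alignment in the 6. All 6 pairings involved the chromosome 1 cluster from 384371 to 386674, and those of chromosome 8 (9 of 18 peaks) and chromosome 1 from 603722 (8 of 16) only just reached 50%. The cluster on chromosome 5 from 180811002 to 180813227 had 15 of 21 peaks in step with that on chromosome 1 from 384371 to 386674, and one on chromosome 6 from 88553 to 90149 had 12 of 16. For the other 4, among them those of chromosome 14 and of chromosome 6 from 170965471, copies elsewhere were not searched for, so a transcript of BT474 at each of these places cannot be told apart from copies. Any copies would count as separate peaks, and their source may be a transcript made in BT474 at 1 of the positions.

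The chromosome 1 cluster from 564660 to 570250 had 8 of 21 BT474 peaks in step with the mitochondrial list, against at most 5 for 6 other clusters. In MCF7 the chromosome 1 cluster had 4 of 18 peaks in step, against at most 4 for 18 other clusters. In MDA-MB-231 it had 5 of 23, against at most 4 for only 2 other clusters, too few for a comparison.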
